A study of Mus musculus with 12 samples.

How the data were processed

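The series holds 12 RNA sequencing libraries of sorted mouse T cells in 4 groups of 3. Per the labels, sorted cells (40000 in each sample) gave RNA through RNeasy Plus Micro columns, cDNA was made with the SMARTer Ultra Low Input kit, and libraries were made with Nextera XT and read as 76 bp pairs. Per the submitters' processing notes, the tools were bcl2fastq 2.17, Trimmomatic, STAR, HTSeq and DESeq2 and the genome build was mm10. The notes give neither their order nor their settings, and the annotation and strand setting are not given in the sources used here.

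A first table holds counts per gene symbol as deposited by the authors, with 48663 gene rows and 5 summary rows of reads not assigned to a gene. A second table, which the authors deposited under the name FPM, holds values equal to CPM of the total over gene rows, and these give the deposited counts back to within 8.1e-05. It leaves out the genes at 0 in all libraries and so holds 26629 rows. Of the symbols 27 read as dates, and these were kept as given but not named. In all 95.5% of symbols matched the GENCODE mouse annotation, release 21, from which the chromosome and position of Zbtb7a were taken.

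Groups were compared with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, 2-sided, on the deposited counts of the 6 libraries of each pair of groups. Genes were filtered with filterByExpr, libraries were scaled with TMM factors, and p-values were adjusted with the Benjamini-Hochberg method at a threshold of 0.05. SEs of log2 fold changes were taken as the fold change over the square root of its F value. CPM printed for a gene are counts over all gene counts without TMM factors.

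The 4 comparisons, the tests, the alternatives, 28 gene lists of T cell functions and of other cell types, and the rule for naming genes were chosen before the data were examined. The rule named, in each comparison, the 10 genes with the largest and the 10 with the smallest log2 fold change among those past the threshold with at least 10 CPM in the higher group and no overlap between groups. It left out receptor and immunoglobulin segments, predicted genes and mitochondrial genes. It added Zbtb7a and, from each list, up to 4 members with the smallest adjusted p, or up to 2 with the highest CPM where fewer than 2 passed. Genes in the text are a part of those the rule named, picked with their values in view. Lists with at least 3 tested members were tested against all other genes with camera of limma 3.58.1 on log2 CPM with a prior count of 2. Camera was run with a preset correlation of 0.01 and, beside it, with a correlation estimated from the libraries.

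Where a group had no counts for a gene, its fold was computed against a floor of 3 counts over the group and is a lower bound. Intervals and floors cover counting error only, since the reads carry no molecular identifiers. The fit was tested on simulated counts with 200 changed genes before it was run on the real ones. For the IELp comparison, with 14391 simulated genes, it recovered 64.1% of genes changed 1.5-fold, 72.3% of those changed 2-fold and 96.9% of those changed 4-fold, and 5.03% of its calls were false. For control IELs against control IELp it recovered 77.4% at 2-fold with 7.69% false calls among 14242 genes, for KO spleen cells against control IELs 71.9% with 2.19% among 13996, and for KO spleen cells against KO IELp 68.2% with 6.80% among 14347. The 200 genes changed up and down alike, with counts drawn from the fitted model. In the real data edgeR called 13.1% of tested genes in the IELp comparison and between 45.0% and 64.8% in the others. The simulated rates therefore need not hold for the real comparisons, least of all where so many genes differ.

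Alternatives were size factors by median of ratios, DESeq2 1.42.0, no filter on low counts, the replicate number as a block, 1 fit of all 12 libraries, limma on the log2 of the authors' FPM values with an added 1 or 0.1, and leaving out each library in turn. Lists without the genes of the sorted proteins were added after the data were seen. Calls shared by 2 comparisons were tested with Fisher's exact test among genes tested in both. Library measures and Zbtb7a were compared with 2-sided exact permutation tests, whose smallest p is 0.1. No library was left out of the comparisons. Xist was found in all 12 libraries, and the 4 Y-linked genes looked at held 1 count in all.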

Results

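RNA sequencing was used to measure gene expression in 4 groups of sorted mouse T cells on the C57BL/6 background, with 3 libraries in each group. Thymic precursors of intraepithelial lymphocytes (IELp) were sorted as TCRβ-positive cells without CD4 or CD8α with CD122 and H-2Kb, with high CD5 and PD-1, and without CD44. They came from mice with floxed Lrf alleles that lacked Cd4-Cre (control) or carried it (KO). Cd4-Cre is a recombinase switched on in developing T cells, and LRF is a zinc finger transcription factor. The other groups were CD8αα T cells, sorted as CD45-positive, TCRβ-positive cells with CD8α but neither CD4 nor CD8β. By their titles, control CD8αα cells were intraepithelial lymphocytes (IELs), which lie in the gut lining, and KO CD8αα cells were splenocytes. The series asks how loss of LRF changes gene expression in the precursors and in CD8αα T cells.

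Between 13432598 and 19947734 counts were assigned to genes in each library. The 10 most abundant genes took 6.33 ± 0.0735% of these counts in control IELs and 3.01 ± 0.0692% in control IELp (SD, n = 3). Counts of ribosomal protein genes made up 0.213 ± 0.00326% in control IELs, against 0.587 ± 0.0268% in control IELp and 0.550 ± 0.0180% in KO spleen cells. Reads that did not map to a unique place are not in these counts, so the shares can understate such transcripts. Levels are in CPM of gene counts, as mean ± SD of the 3 libraries of a group (n = 3). Fold changes come from the edgeR model, which also scales the libraries, so they differ slightly from the ratio of 2 CPM values. The labels do not state that replicates came from separate animals, so the p-values measure only the spread between these samples, part of which may be technical.

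Zbtb7a, the gene that encodes LRF (chromosome 10, 81135220 to 81152995, plus strand, mm10), was measured first in every sample as a check of the labels. It stood at 75.4 ± 6.27 CPM in control IELp and 45.5 ± 4.66 CPM in KO IELp, and at 111 ± 8.91 CPM in control IELs and 61.3 ± 2.13 CPM in KO spleen cells. Every KO IELp library (42.0 to 50.8 CPM) lay below every control IELp library (68.5 to 80.7 CPM), and the KO spleen libraries (59.1 to 63.4 CPM) lay below the control IEL libraries (101 to 119 CPM). The fall in IELp passed the gene test (log2 fold change -0.71, SE 0.10, edgeR adjusted p = 1.56e-04), and a two-sided exact permutation test gave p = 0.1, the smallest that 3 against 3 libraries allow. Transcript remained in the KO groups. The labels do not say which exons were floxed, and a transcript that lost only part of the gene would still be counted.

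**Figure D1:**
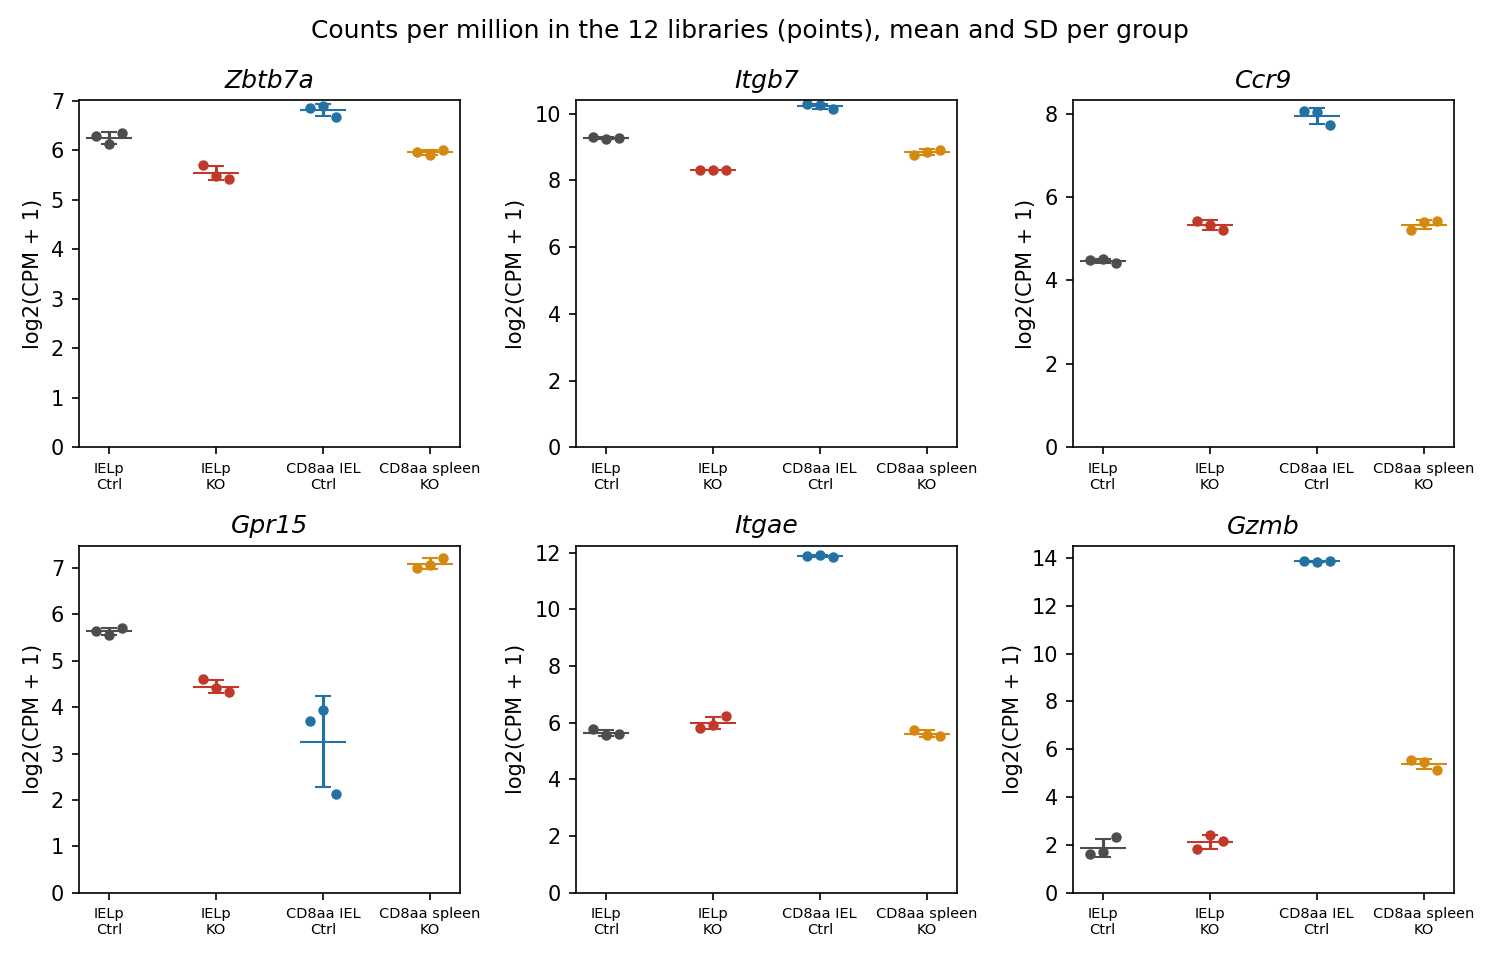
Expression of 6 genes as log2(CPM + 1), in log2 units on the vertical axis, in the 4 groups of 3 libraries. Points are libraries and bars are the mean and SD of the log2 values; Zbtb7a and Itgb7 lie lower in KO IELp than in control IELp, and Itgae and Gzmb are highest in control IELs.

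The comparison of KO with control IELp is the one in which genotype alone differed. Genes of homing receptors moved in both directions in KO IELp. Itgb7, the β7 chain of the gut-homing integrin α4β7, fell from 620.0 ± 14.1 to 319 ± 0.853 CPM (log2 fold change -0.94, SE 0.04, edgeR adjusted p = 4.16e-09). Gpr15, a receptor for homing to the large intestine, fell from 48.8 ± 2.72 to 20.8 ± 2.21 CPM. Ccr9, the receptor for the small-intestinal chemokine CCL25, moved the other way and rose from 21.2 ± 0.808 to 39.1 ± 3.25 CPM (log2 fold change 0.90, SE 0.10, edgeR adjusted p = 3.27e-05). Of 23 tested homing and trafficking genes, 6 fell and 3 rose, and adjusted over the list alone 9 fell and 5 rose (camera adjusted p = 0.0245, and adjusted p = 0.255 with an estimated correlation).

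Interferon-response genes were lower in KO IELp. Of 36 tested, 26 fell and 10 did not pass, and 30 fell adjusted over the list alone (camera adjusted p = 5.81e-18, and adjusted p = 0.133 with an estimated correlation). Ifit1, an interferon-induced protein that binds foreign RNA, fell from 46.5 ± 11.1 to 21.4 ± 3.00 CPM, Zbp1, a sensor of nucleic acids, fell from 59.3 ± 6.06 to 35.4 ± 1.86 CPM, and Ifi27l2a fell from 43.2 ± 5.04 to 17.2 ± 1.24 CPM.

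**Figure D2:**
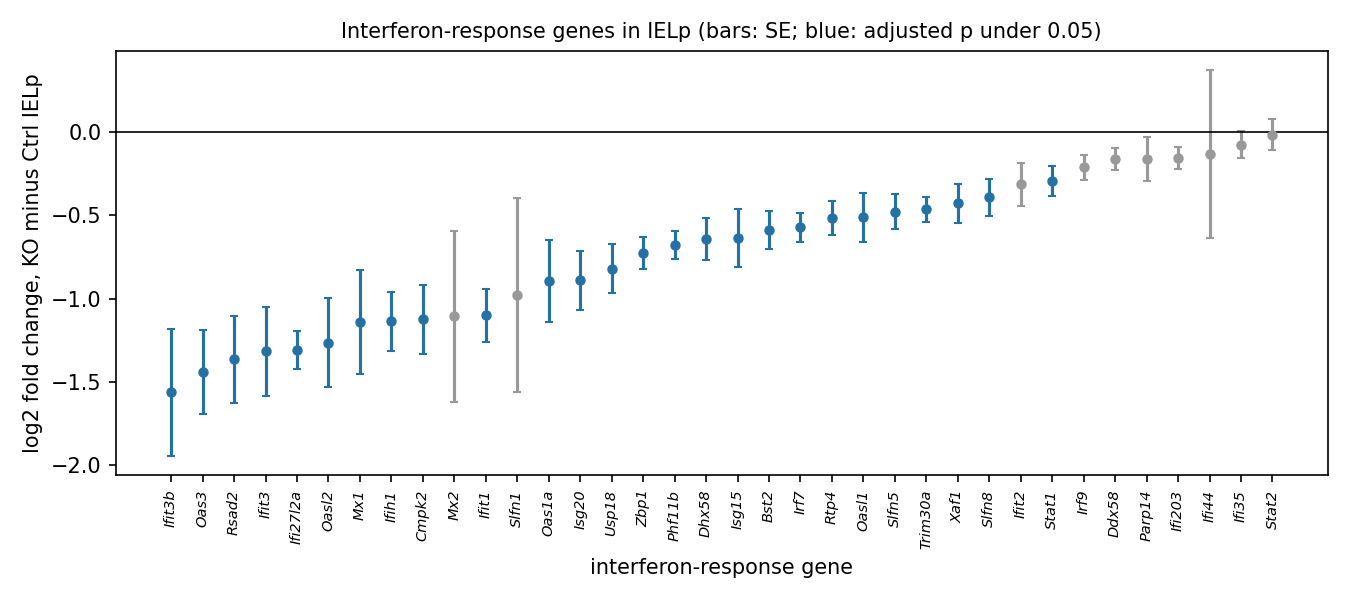
Fold change (log2, KO minus control IELp, edgeR) of the 36 tested interferon-response genes, one point per gene with its SE, in order of size. Blue points are the 26 genes with an adjusted p under 0.05, all below 0; grey points are the 10 that did not pass.

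Genes of the cell cycle also fell. Of 40 tested proliferation genes, 21 fell, and 23 did so adjusted over the list alone (camera adjusted p = 6.90e-11, and adjusted p = 0.133 with an estimated correlation). Examples are Rrm2, a subunit of the enzyme that makes deoxyribonucleotides (132 ± 8.24 CPM against 202 ± 5.08), and Ube2c, which acts in mitotic exit (24.9 ± 2.20 CPM against 46.5 ± 2.23). Among 18 tested NK receptor genes and adaptors, 8 fell, and 9 adjusted over the list alone (camera adjusted p = 2.60e-04, and adjusted p = 0.133 with an estimated correlation). Hcst, which encodes the signalling adaptor DAP10, fell from 13.7 ± 2.38 to 4.29 ± 1.30 CPM and Crtam from 49.9 ± 3.46 to 32.8 ± 2.55 CPM. Of the 100 genes highest in KO spleen cells over all IELp libraries, 31 fell and 19 rose in KO IELp. Their median log2 fold change of -0.286 lay below the lowest of 10000 lists matched on expression (-0.203). Only the interferon list was kept out of this set. It can therefore share members with the NK receptor and naive lists and is no separate support for them. Of 34 genes tied to strong T cell receptor signals, 12 fell and 1 rose, or 12 and 3 adjusted over the list alone (camera adjusted p = 0.00286, and adjusted p = 0.214 with an estimated correlation). The costimulatory receptor Icos fell from 55.5 ± 4.94 to 27.2 ± 0.965 CPM and the transcription factor Batf from 22.7 ± 1.15 to 12.04 ± 2.06 CPM.

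Genes of naive and quiescent T cells fell more often than they rose in KO IELp. The list gave 10 lower and 3 higher of 22 tested, or 11 and 4 adjusted over the list alone (camera adjusted p = 0.0104, and adjusted p = 0.133 with an estimated correlation). Slfn2, which helps to keep T cells quiescent, fell from 148 ± 9.16 to 78.5 ± 5.32 CPM, and Id3, an inhibitor of E proteins, fell from 737 ± 19.7 to 534 ± 20.6 CPM. Some glycolysis genes rose. Of 23, 9 rose and 1 fell, or 10 and 2 adjusted over the list alone (camera adjusted p = 4.73e-04, and adjusted p = 0.133 with an estimated correlation). The changes were small: Pkm, which encodes pyruvate kinase, rose from 783 ± 23.4 to 1010.2 ± 10.9 CPM, and Pfkp, a phosphofructokinase, rose from 389 ± 4.80 to 492 ± 5.85 CPM. For mitochondrial respiration, 3 of 61 genes fell (camera adjusted p = 0.00454, and adjusted p = 0.609 with an estimated correlation). Adjusted over the list alone with edgeR the count was 0, with 8 genes lower at an unadjusted p under 0.05 and 3 by DESeq2.

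Genes outside these lists changed too. Pth1r, a parathyroid hormone receptor, stood at 11.6 ± 1.20 CPM against 0.160 ± 0.119 in KO over control IELp, Tpm2, a muscle tropomyosin, at 35.9 ± 1.85 CPM against 0.588 ± 0.335, and Igf2, a growth factor, at 20.5 ± 2.12 CPM against 1.32 ± 1.54. Notch3, a Notch receptor, rose from 2.99 ± 1.66 to 47.2 ± 11.4 CPM (log2 fold change 4.02, SE 0.26, edgeR adjusted p = 1.01e-07), while Dtx1, a known Notch target, fell from 17.5 ± 4.45 to 4.44 ± 0.982 CPM. The matrix-linked genes Rcn3 and Cpxm1 rose from 4.29 ± 1.03 to 47.3 ± 3.16 CPM and from 0.917 ± 0.604 to 10.9 ± 0.337 CPM. Cd83, a surface marker of activated and selected lymphocytes, fell from 20.7 ± 3.75 to 2.16 ± 0.305 CPM (log2 fold change -3.24, SE 0.19, edgeR adjusted p = 4.93e-08). Ms4a4b and Ms4a6b, which belong to a family of similar genes and are uncertain for that reason, fell from 167 ± 6.91 to 59.5 ± 7.92 CPM and from 91.4 ± 5.71 to 27.7 ± 2.92 CPM.

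In all, 948 genes were higher and 963 lower in KO than in control IELp of 14629 tested (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). At least 2-fold changes made up 200 of the higher and 218 of the lower genes. The 2 groups did not overlap in 29.7% of tested genes, where chance gives 10%. The counts depended on single libraries: 591 genes were higher without KO IELp replicate 2 and 615 without KO IELp replicate 3, and 635 were lower without control IELp replicate 2. Of 12 markers of regulatory T cells 4 fell, or 7 adjusted over the list alone (camera adjusted p = 0.00117, and adjusted p = 0.133 with an estimated correlation), and of 9 of invariant T cells 4 fell and 1 rose, the same adjusted over the list alone (camera adjusted p = 0.0186, and adjusted p = 0.213 with an estimated correlation). Most of the 4 regulatory T cell calls were lost in some fits without 1 library (edgeR adjusted p up to 0.261). Together 10 lists passed camera with the preset correlation, and their smallest adjusted p with a correlation estimated from these libraries was 0.133 with camera. Without 1 control IELp replicate some calls were lost: homing without replicate 1 (camera adjusted p = 0.0530) or 3 (0.0654), respiration without replicate 3 (0.221) and invariant T cell markers without replicate 2 (0.0806).

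**Figure D3:**
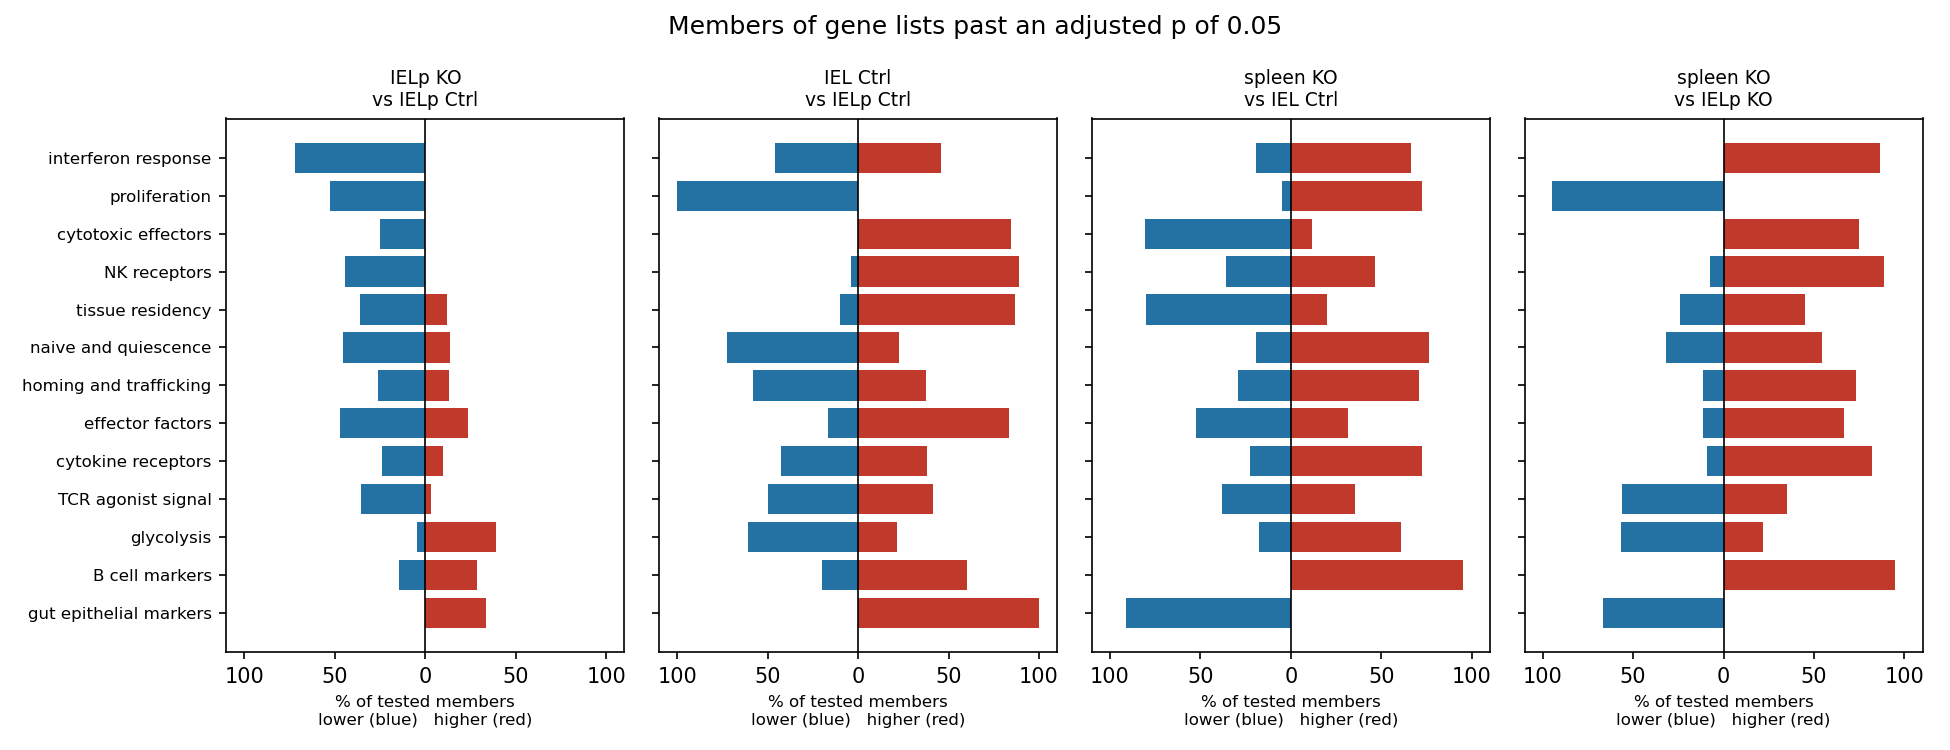
Share of the tested members of 13 gene lists that were lower (blue, left) or higher (red, right) at an edgeR adjusted p under 0.05, in percent on the horizontal axis, for the 4 comparisons. All 40 proliferation genes were lower in control IELs than in control IELp, and 38 of 40 were lower in KO spleen cells than in KO IELp.

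Control CD8αα IELs were next compared with control IELp, cells of the same genotype that differ in stage and tissue. The sample numbers of the IELp and CD8αα libraries form separate blocks. A difference in processing between the blocks, if any, cannot be told apart from stage and tissue, here or between the KO groups. The IELs held the cytotoxic granule genes Gzmb and Gzma among their most abundant transcripts. Gzmb stood at 14836 ± 264 CPM against 2.78 ± 1.04 and Gzma at 14786 ± 634 CPM against 4.04 ± 1.10, and Fasl, which encodes a death-inducing ligand, rose from 9.79 ± 1.51 to 707 ± 23.6 CPM. Itgae, the αE integrin chain that binds E-cadherin on epithelium, rose from 48.9 ± 3.85 to 3775 ± 81.1 CPM (log2 fold change 6.50, SE 0.08, edgeR adjusted p = 1.52e-12). Itga1, which encodes the collagen-binding α1 integrin chain, and Prdm1, which encodes the transcription factor Blimp-1, had no counts in control IELp. They reached 748 ± 83.6 and 195 ± 20.4 CPM in IELs, and Prdm1 was at least 2917-fold higher when 3 counts over the group are taken as the floor.

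Of 26 cytotoxic effector genes, 22 rose in IELs, and 22 adjusted over the list alone (camera adjusted p = 4.73e-11, and adjusted p = 0.0267 with an estimated correlation). NK receptors and adaptors followed, with 24 of 27 higher and 1 lower, or 25 and 1 adjusted over the list alone (camera adjusted p = 1.25e-10, and adjusted p = 0.0232 with an estimated correlation). Klrd1, which encodes CD94, rose from 7.36 ± 1.59 to 881 ± 52.2 CPM and Slamf7 from 2.83 ± 0.254 to 173 ± 5.89 CPM. Tissue-residency genes gave 26 higher and 3 lower of 30, with the same counts adjusted over the list alone (camera adjusted p = 2.44e-10, and adjusted p = 0.0218 with an estimated correlation). Rgs1, which dampens chemokine receptor signals, rose from 17.0 ± 1.19 to 6413 ± 183 CPM. Among transcription factors of effector and memory cells, 15 rose and 3 fell of 18, with the same counts adjusted over the list alone (camera adjusted p = 1.33e-05, and adjusted p = 0.0376 with an estimated correlation). Tbx21, which encodes T-bet, rose from 19.98 ± 1.86 to 286 ± 5.95 CPM and Bhlhe40 from 6.27 ± 0.212 to 241 ± 5.63 CPM.

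Naive and quiescence genes were lower in IELs, with 16 lower and 5 higher of 22, the same adjusted over the list alone (camera adjusted p = 3.15e-04, and adjusted p = 0.0474 with an estimated correlation). Lef1 and Satb1, factors of early T cells, fell from 668 ± 10.4 to 12.1 ± 1.73 CPM and from 399 ± 8.41 to 14.9 ± 0.849 CPM. S1pr1, the receptor for exit from lymphoid organs, fell from 276 ± 16.1 to 2.27 ± 0.435 CPM, and Klf2, its transcriptional activator, fell from 374 ± 25.7 to 5.51 ± 0.589 CPM. All 40 tested proliferation genes were lower, also adjusted over the list alone (camera adjusted p = 1.29e-16, and adjusted p = 0.0218 with an estimated correlation), and Top2a, a topoisomerase of dividing cells, fell from 247 ± 10.1 to 40.0 ± 1.80 CPM. Egr2, induced by T cell receptor signals, fell from 163 ± 7.43 to 7.75 ± 0.352 CPM, while the list of such genes split into 14 higher and 17 lower of 34, the same adjusted over the list alone (limma camera adjusted p = 0.379). Without Cd5 and Pdcd1, on which the cells were sorted, it gave 14 higher and 15 lower of 32.

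Metabolic genes were lower in IELs, but those calls rested on the preset correlation. Respiration genes gave 45 lower and 3 higher of 61, or 46 and 3 adjusted over the list alone (camera adjusted p = 1.09e-05, and adjusted p = 0.467 with an estimated correlation). Transcripts of the mitochondrial genome made up 0.312 ± 0.0176% of gene counts in control IELs, 0.539 ± 0.0339% in control IELp and 0.682 ± 0.0611% in KO spleen cells (n = 3). Glycolysis genes gave 14 lower and 5 higher of 23, or 14 and 6 adjusted over the list alone (camera adjusted p = 0.0438, and adjusted p = 0.348 with an estimated correlation). Dntt and Arpp21, markers of earlier double-positive thymocytes, had no counts in IELs and were at least 202-fold and at least 132-fold lower. Of 13 such markers 9 fell and 3 rose, the same adjusted over the list alone (camera adjusted p = 0.0467, and adjusted p = 0.230 with an estimated correlation). This call was lost without Cd4 and Cd8b1, on which the cells were sorted (camera adjusted p = 0.113), without control IEL replicate 3 (camera adjusted p = 0.0700) and with the replicate number as a block (camera adjusted p = 0.0570). One that rose was Ccr9 (246 ± 30.7 CPM against 21.2 ± 0.808).

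Some markers from lists of other cell types were higher in the IEL libraries, which does not by itself show that such cells were present. The myeloid markers Adgre1, C1qa and C1qb were at 0 CPM in control IELs. Their means in control IELp were at most 0.506 CPM, so they tell little about a difference between these groups. Of 13 myeloid markers 9 rose, or 10 adjusted over the list alone (camera adjusted p = 9.39e-05, and adjusted p = 0.0474 with an estimated correlation), such as Tyrobp (358 ± 53.9 CPM against 6.69 ± 0.904). Of 7 NK and innate lymphoid markers 6 rose and 1 fell, the same adjusted over the list alone (camera adjusted p = 0.0157, and adjusted p = 0.212 with an estimated correlation). For gut epithelial cells, all 11 tested rose, also adjusted over the list alone (camera adjusted p = 4.81e-04, and adjusted p = 0.420 with an estimated correlation), and their sum was 154.6, 156.6 and 313 CPM in control IEL replicates 1, 2 and 3. Without replicate 3, 25 residency, 23 cytotoxic and 25 NK receptor genes were higher, and 16 naive and 39 proliferation genes lower. Among early-response genes that can rise during tissue dissociation, Junb (2376 ± 138 CPM against 197 ± 19.7) and Dusp1 (1449.7 ± 211 CPM against 46.6 ± 7.99) were higher in IELs, but the list went both ways and did not pass (11 higher and 7 lower of 21, the same adjusted over the list alone, limma camera adjusted p = 0.0973).

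Over all genes, 4742 were higher and 4897 lower in control IELs than in control IELp of 14878 tested with edgeR, and the groups did not overlap in 70.9% of them (10% by chance). The split depended on the scaling: 34.7% of called genes were higher with limma on the authors' FPM values, which use total counts alone, against 49.2% with edgeR's scaling, and the median of all genes lay -0.20 on the log2 scale away from the edgeR median. Genes of the sorted proteins, such as Cd8a and Pdcd1, differed by the sort itself and are no findings here or in the comparison of the KO groups.

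KO spleen CD8αα cells were compared with control CD8αα IELs through the same sort, but genotype and tissue differed together, so the comparison cannot separate them. Residency and granule transcripts that marked IELs were low in the spleen cells. Itgae stood at 48.1 ± 4.12 CPM against 3775 ± 81.1, Rgs1 at 35.6 ± 3.77 CPM against 6413 ± 183 and Gzmb at 40.9 ± 6.11 CPM against 14836 ± 264. S1pr1 was high in their place, at 385 ± 2.53 CPM against 2.27 ± 0.435 (log2 fold change 7.29, SE 0.11, edgeR adjusted p = 5.81e-11).

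Tissue-residency genes fell in 24 and rose in 6 of 30 cases, the same adjusted over the list alone (camera adjusted p = 2.85e-08, and adjusted p = 0.0354 with an estimated correlation). Cytotoxic effectors gave 21 lower and 3 higher of 26, the same adjusted over the list alone (camera adjusted p = 1.02e-07, and adjusted p = 0.0354 with an estimated correlation), with Prf1, which encodes perforin, at 32.1 ± 1.31 CPM against 245 ± 12.5. The naive and quiescence list moved up, with 16 higher and 4 lower of 21, the same adjusted over the list alone (camera adjusted p = 4.07e-06, and adjusted p = 0.0355 with an estimated correlation). Lef1 rose from 12.1 ± 1.73 to 441 ± 16.3 CPM, Satb1 from 14.9 ± 0.849 to 387 ± 5.94 CPM and Klf2 from 5.51 ± 0.589 to 264 ± 2.87 CPM. Eomes, a transcription factor of memory T and NK cells, rose from 1.04 ± 0.00801 to 92.2 ± 2.14 CPM, whereas Ahr, a receptor that maintains gut lymphocytes, fell from 133 ± 2.54 to 42.2 ± 1.08 CPM.

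Several other lists passed only with the preset correlation. Homing genes gave 17 higher and 7 lower of 24, the same adjusted over the list alone (camera adjusted p = 0.00996, and adjusted p = 0.186 with an estimated correlation). Interferon-response genes gave 24 higher and 7 lower of 36, the same adjusted over the list alone (camera adjusted p = 0.00155, and adjusted p = 0.286 with an estimated correlation). For example, Usp18, a brake on interferon signalling, rose from 3.66 ± 0.356 to 40.3 ± 3.28 CPM. Proliferation genes gave 29 higher and 2 lower of 40, the same adjusted over the list alone (camera adjusted p = 9.77e-06, and adjusted p = 0.313 with an estimated correlation), among them Mcm3, part of the replicative helicase (214 ± 27.5 CPM against 79.2 ± 5.85). Cytokine receptors gave 16 higher and 5 lower of 22, the same adjusted over the list alone (camera adjusted p = 0.00430, and adjusted p = 0.186 with an estimated correlation), with the interleukin 7 receptor chain Il7r at 74.0 ± 5.29 CPM against 6.85 ± 2.05.

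B cell genes were present in the spleen libraries, although the sort took TCRβ-positive cells. Of 20 tested markers 19 rose, the same adjusted over the list alone (camera adjusted p = 7.26e-09, and adjusted p = 0.0354 with an estimated correlation). Ms4a1, which encodes CD20, had no counts in control IELs and was 12.6 ± 0.973 CPM in spleen cells, at least 212-fold higher, and Cd22 was 100.02 ± 12.8 CPM against 5.39 ± 1.41. The haemoglobin gene Hbb-bs was 5.56, 5.35 and 0.223 CPM in KO spleen replicates 1, 2 and 3, and the immunoglobulin gene Igkc 16.8, 16.6 and 7.22 CPM. Of 19 myeloid markers 8 rose and 8 fell (camera adjusted p = 0.852), with C1qb at 5.31 ± 2.41 CPM against 0 in control IELs. NK and innate lymphoid markers gave 6 higher and 2 lower of 9, the same adjusted over the list alone (camera adjusted p = 0.0291, and adjusted p = 0.202 with an estimated correlation). Gut epithelial markers gave 10 lower of 11, or 11 adjusted over the list alone (camera adjusted p = 4.54e-04, and adjusted p = 0.313 with an estimated correlation). Without control IEL replicate 3, 24 residency and 22 cytotoxic genes were lower and 18 naive genes higher. The early-response genes Fos and Junb were 11.6 ± 1.34 CPM against 801 ± 27.1 and 133 ± 15.6 CPM against 2376 ± 138 in spleen cells over IELs, but their list of dissociation genes went both ways and did not pass (7 higher and 12 lower of 22, the same adjusted over the list alone, limma camera adjusted p = 0.0614).

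Among single genes, Spp1, which encodes osteopontin, and Ahrr, the repressor of the aryl hydrocarbon receptor, had no counts in KO spleen cells and were at least 1377-fold and at least 1206-fold lower than in IELs. Glp1r, the receptor for the gut hormone GLP-1, was likewise at least 2538-fold lower. Maged1 and Crhbp had no counts in IELs and were at least 1155-fold and at least 847-fold higher. Ly6c2, a member of a family of similar genes and uncertain for that reason, rose from 0.200 ± 0.131 to 754 ± 12.6 CPM. edgeR called 4323 genes higher and 4337 lower of 14875 tested, and 66.2% of tested genes did not overlap between the groups (10% by chance). With limma on the authors' FPM values 59.4% of called genes were higher in place of 49.9%, and the median of all genes shifted by 0.11 on the log2 scale.

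KO spleen CD8αα cells were last compared with KO IELp, which share the genotype and differ in stage and tissue. NK receptors set the spleen cells apart. Klrk1, which encodes the activating receptor NKG2D, had no counts in KO IELp and was 275 ± 19.7 CPM in spleen cells, at least 4601-fold higher. Klrd1 rose from 5.27 ± 0.810 to 510.5 ± 2.53 CPM (log2 fold change 6.72, SE 0.08, edgeR adjusted p = 5.62e-15), and the inflammatory chemokine receptor Cxcr3 rose from 1.02 ± 0.138 to 377 ± 9.82 CPM. Ccl5, a chemokine of effector cells, rose from 12.7 ± 3.34 to 806 ± 12.1 CPM, while Spry1, a feedback inhibitor of receptor signalling, fell from 51.3 ± 3.87 to 0.947 ± 0.282 CPM.

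Of 27 NK receptors and adaptors, 24 rose and 2 fell, the same adjusted over the list alone (camera adjusted p = 1.02e-17, and adjusted p = 0.0163 with an estimated correlation). Klra7 and Klra6 rose from 2.12 ± 0.773 to 413 ± 10.7 CPM and from 1.86 ± 0.483 to 208 ± 6.27 CPM, and as members of a family of near-identical genes they are uncertain individually. Cytotoxic effectors rose in 18 of 24 cases, or 20 adjusted over the list alone (camera adjusted p = 1.06e-10, and adjusted p = 0.0186 with an estimated correlation), for example Nkg7 (1042 ± 22.3 CPM against 267 ± 12.1). Homing genes gave 19 higher and 3 lower of 26, or 19 and 4 adjusted over the list alone (camera adjusted p = 2.13e-08, and adjusted p = 0.0252 with an estimated correlation), with Itgal, the α chain of the adhesion integrin LFA-1, at 1179.8 ± 12.6 CPM against 559.5 ± 16.5. Cytokine receptors gave 18 higher and 2 lower of 22, the same adjusted over the list alone (camera adjusted p = 1.77e-08, and adjusted p = 0.0186 with an estimated correlation), or 17 and 2 of 21 without Il2rb, on which IELp were sorted. Among them Il18rap, a chain of the interleukin 18 receptor, rose from 0.540 ± 0.177 to 138 ± 8.79 CPM and Ifngr1 from 319 ± 9.16 to 1278 ± 17.6 CPM.

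Effector and memory factors gave 12 higher and 2 lower of 18, the same adjusted over the list alone (camera adjusted p = 1.95e-04, and adjusted p = 0.0521 with an estimated correlation), and Tbx21 rose from 27.2 ± 8.23 to 694 ± 19.1 CPM. Interferon-response genes rose in 32 of 37 cases, or 33 adjusted over the list alone (camera adjusted p = 1.01e-14, and adjusted p = 0.0875 with an estimated correlation), such as Irf7, the factor that amplifies interferon production (129 ± 2.37 CPM against 59.6 ± 2.97). Proliferation genes fell in 38 of 40 cases, the same adjusted over the list alone (camera adjusted p = 2.84e-17, and adjusted p = 0.159 with an estimated correlation), with Mcm6 falling from 1113 ± 39.9 to 535 ± 26.3 CPM. Genes of strong T cell receptor signals gave 19 lower and 12 higher of 34, the same adjusted over the list alone (camera adjusted p = 0.0456, and adjusted p = 0.235 with an estimated correlation). This call was lost without Cd5 and Pdcd1 (17 lower and 12 higher of 32, camera adjusted p = 0.129), without KO spleen replicate 1 (camera adjusted p = 0.0535) and with the replicate number as a block (camera adjusted p = 0.0511). Nr4a1, an immediate target of such signals, fell from 544 ± 39.2 to 139 ± 5.27 CPM and Tnfrsf9 from 453 ± 3.97 to 107 ± 0.979 CPM. Glycolysis genes gave 13 lower and 5 higher of 23, or 14 and 5 adjusted over the list alone (camera adjusted p = 0.0352, and adjusted p = 0.235 with an estimated correlation).

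Other cell type markers moved as well. NK and innate lymphoid markers rose in all 9 tested cases (camera adjusted p = 1.18e-09, and adjusted p = 0.0186 with an estimated correlation), B cell markers in 19 of 20 (camera adjusted p = 4.48e-14, and adjusted p = 0.0163 with an estimated correlation) and myeloid markers in 15 of 18 (camera adjusted p = 1.64e-07, and adjusted p = 0.0186 with an estimated correlation), all 3 with the same counts adjusted over the list alone. Cd22 rose from 0.505 ± 0.230 to 100.02 ± 12.8 CPM and Tyrobp, which encodes the NK and myeloid adaptor DAP12, rose from 8.90 ± 1.77 to 86.2 ± 4.54 CPM. Because the spleen libraries also held B cell and haemoglobin transcripts, these rises need not come from the CD8αα T cells. With edgeR, 3370 genes were higher and 3330 lower in KO spleen cells of 14880 tested, and 56.4% of tested genes did not overlap between groups (10% by chance). With the authors' FPM values, 35.7% of called genes were higher in place of 50.3%, and the median of all genes shifted by -0.10 on the log2 scale.

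Genes that differed by genotype in IELp were then followed between KO spleen cells and control IELs, in fits that share no library. Of 13921 genes tested in both, 925 were higher in KO IELp, and 475 of these were also higher in KO spleen cells, where independent lists would share 275 (Fisher's exact test, odds ratio 2.69, p = 3.20e-46). Of 914 genes lower in KO IELp, 388 were also lower in KO spleen cells, where independent lists would share 257 (odds ratio 1.99, Fisher's exact test p = 5.34e-22). Of the genes higher in KO IELp 233 were lower in KO spleen cells, where independent lists would share 259.7 (odds ratio 0.854), and of those lower in KO IELp 307 were higher there, where independent lists would share 271 (odds ratio 1.21, Fisher's exact test p = 0.00873). Genes lower in KO IELp were thus over-represented in both directions. Genes are not independent of one another, so these p-values are too small. Tested as sets, the genes higher in KO IELp were higher in KO spleen cells (camera p = 5.91e-05, and p = 2.36e-04 with an estimated correlation), while those lower in KO IELp did not pass with the preset correlation (camera p = 0.170, and p = 0.0317 with an estimated correlation). Rcn3 and Cpxm1 rose in KO IELp, and Cpxm1 was also at least 336-fold higher in KO spleen cells than in control IELs, where it had no counts.

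Genes that separated CD8αα cells from IELp in controls were compared with those that did so in KO mice. Among 14256 genes tested in both comparisons, 1813 were higher in both, where independent lists would share 967 (odds ratio 4.49, Fisher's exact test p = 5.12e-281), and 2063 were lower in both, where independent lists would share 1108 (odds ratio 5.07). These were 41.8% of the 4338 genes higher and 42.7% of the 4826 lower in controls, and 457 and 560 went in the opposite direction in KO mice. Klrd1, Tbx21 and Gpr18 were higher in both: Gpr18, a G protein-coupled receptor of IELs, rose from 16.7 ± 1.33 to 453 ± 39.8 CPM in controls and from 11.0 ± 1.11 to 150.2 ± 5.99 CPM in KO cells. The tissue of the CD8αα cells differed between the 2 comparisons.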

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

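The tests of reads not used in the comparisons were chosen after these values were seen. Reads that mapped to more than 1 place made up 16.8% of the table in KO spleen CD8αα cells and 13.3% in control IELs, a difference in data outside the gene counts (2-sided exact permutation test p = 0.1, the smallest that 3 against 3 libraries allow). Reads that overlapped more than 1 gene made up 0.746% and 0.715% (exact permutation p = 0.1). Both differences are between groups of different tissue and genotype, and no explanation was tested. In control IELp and KO IELp, reads that mapped to more than 1 place made up 18.1% and 17.0%, so control IELs had the lowest share of all groups. They also lay below control IELp, which have the same genotype (exact permutation p = 0.1). Counts of ribosomal protein genes, which have many similar copies in the genome, were also higher in the spleen libraries (0.550% against 0.213% of gene counts, exact permutation p = 0.1). Reads that mapped to more than 1 place are not among these counts, so they can understate such transcripts.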

How the results depend on the processing

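The counts without control IEL replicate 3 in the report, the lists without genes of the sort and the refits of single genes without 1 library were chosen after the data were seen; the other alternatives were not. Of 185 alternatives for the main results, 178 left the result in its direction and within 1.5 times its value, and 7 moved it. For genes and lists this compares only how many were called, not which. In KO against control IELp, 1 fit of all 12 libraries called 1358 genes and kept 68.1% of the 1911 calls. The replicate number as a block kept 79.2%. With a correlation estimated from the libraries, the number of lists past camera's threshold fell from 10 to 0 in KO against control IELp (6 of the 10 had an unadjusted p under 0.05), from 14 to 7 in control IELs against IELp, from 14 to 4 in KO spleen cells against control IELs and from 13 to 7 in KO spleen cells against KO IELp. The cause was not tested. With 1 library left out, genes higher in KO IELp ranged from 591 (without KO replicate 2) to 871 and genes lower from 635 (without control replicate 2) to 939 with edgeR, and 615 were higher without KO replicate 3. These fits have fewer libraries. Leaving out 1 library also ended list calls besides those in the report: regulatory T cell markers in control IELs against IELp without control IELp replicate 1 (camera adjusted p = 0.0633) or 3 (0.0525), thymic stroma markers in KO spleen cells against control IELs without control IEL replicate 3 (0.0839), and gut epithelial markers in KO spleen cells against KO IELp without KO spleen replicate 1 (0.0535) or 3 (0.0580). Without genes of the sort, 11 of 14 lists passed in control IELs against IELp and 12 of 13 in KO spleen cells against KO IELp.

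With the replicate number as a replicate block, 760 genes were higher and 781 lower in KO than in control IELp, 4721 and 4845 in control IELs than in IELp, 4062 and 4098 in KO spleen cells than in control IELs, and 3277 and 3272 in KO spleen cells than in KO IELp. The lists past camera's threshold with this block numbered 12, 12, 14 and 12 in the same order. It ended the calls of double-positive thymocyte markers (adjusted p = 0.0570) and regulatory T cell markers (0.0596) in control IELs against IELp and of T cell receptor signal genes (0.0511) in KO spleen cells against KO IELp. In KO against control IELp it added the calls of cytokine receptors (0.0388) and dissociation stress genes (0.0419). Correlations between libraries that share a number were at most 0.0647, and the main fits left the samples unpaired. In control IELs against IELp and in KO spleen cells against KO IELp, 6 of 6 samples correlated best with their own number. The lowest correlation within a number there was 0.0307 and 0.0221, against a highest of 0.0292 and 0.00548 across numbers. In the other comparisons 0 of 6 and 1 of 6 samples did so. A pairing or a shared batch by number can therefore not be excluded in the comparisons within a genotype. Zbtb7a stayed lower in KO IELp when any library was left out, by a log2 fold change between -0.79 and -0.65. Of 428 gene results that the naming rule gave, 19 lost their call when 1 library was left out. Nearly all of these were in KO against control IELp. There, fits without 1 library kept between 61.7% and 79.1% of the 1911 calls. None of the 19 is among the 104 gene results in the text, because genes were picked for the text with this in view, so the stability of those 104 says nothing about genes at large.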

Other observations

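All tests of explanations in this part were chosen after the results were seen. Among genes of dissociation stress, 6 of 21 rose and 2 fell in KO IELp, or 7 and 3 adjusted over the list alone, and the list did not pass (camera adjusted p = 0.0558, and adjusted p = 0.214 with an estimated correlation). Hspa1b, an inducible chaperone that shares most of its sequence with Hspa1a and is uncertain for that reason, was 15.0 ± 4.68 CPM against 2.03 ± 0.424 in KO over control cells (n = 3). The chaperone gene Hsp90ab1 was 2168 ± 39.8 CPM against 1816 ± 13.5 and Hsph1 238 ± 5.54 CPM against 182 ± 13.7 (edgeR adjusted p = 3.95e-04). Sdc1, which encodes the heparan sulfate carrier syndecan-1, rose from 26.8 ± 1.48 to 67.7 ± 2.86 CPM (log2 fold change 1.36, SE 0.09, edgeR adjusted p = 1.39e-07). Cd8a stood at 46.5 ± 3.06 CPM against 18.7 ± 1.36 and Cd4 at 1.99 ± 0.575 CPM against 7.42 ± 2.16, although both sorts excluded cells with either protein.

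Some genes of effector molecules and cytokine receptors fell in KO IELp, and their lists did not pass. Xcl1, a chemokine that attracts dendritic cells, fell from 43.8 ± 2.81 to 18.0 ± 0.517 CPM (log2 fold change -1.27, SE 0.10, edgeR adjusted p = 8.25e-07), and Cst7, an inhibitor of granule proteases, fell from 69.1 ± 4.29 to 37.0 ± 2.99 CPM. Il4ra, a chain of the interleukin 4 receptor, fell from 117 ± 3.80 to 67.7 ± 10.2 CPM. Of 20 cytotoxic effectors 5 fell, or 5 adjusted over the list alone (limma camera adjusted p = 0.0567), and of 21 cytokine receptors 5 fell and 2 rose, or 5 and 2 adjusted over the list alone (limma camera adjusted p = 0.0520). Pmepa1, a target of TGFβ signals, rose from 19.2 ± 1.58 to 27.6 ± 0.910 CPM, 1 of 4 of 20 TGFβ response genes that rose, also adjusted over the list alone (limma camera adjusted p = 0.299). The other calls among these 4 were lost in 4 or 5 of the 6 fits that left out 1 library.

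Interferon-response genes were lower in KO IELp. A fall of all genes at their level is excluded, since the lowest median log2 fold change of 10000 lists matched on expression was -0.171 and the interferon list's was -0.64. A single library is not the source, since between 18 and 25 of these genes fell with any 1 library left out, against 26 with all. Fewer mature T cells among the KO precursors remain a candidate, although the sort excluded CD4, CD8α and CD44. The 100 genes highest in KO spleen cells over all 6 IELp libraries, outside the interferon list, had a median of -0.286 (31 lower, 19 higher). The lowest of 10000 matched lists was -0.203. These genes were ranked by level alone in libraries that also held B cell transcripts, so the set is not specific to mature T cells. A lower median therefore cannot tell whether such cells were fewer. That test replaced an earlier one that ranked genes against control IELp alone, in which the control libraries entered both measures, and the effect of genotype within 1 cell type stays open beside it.

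In KO IELp 89 genes rose at least 4-fold, Pth1r and Notch3 among them, and their summed level went from 279 to 1640 CPM. Markers of thymic stromal and epithelial cells gave no sign of such cells, since 12 low-level markers differed by -0.178 CPM in sum (SD 0.462). The raised genes gained 1360 CPM. How much of these markers such a cell would bring beside the raised genes is not known, so the sum cannot exclude this source. Of 14 markers Pecam1 and Ccl25 were left out of this sum after their levels in the control cells were seen. Of the 72 raised genes tested between KO spleen cells and control IELs, 50 (69.4%) were higher there and 14 were lower. In 10000 matched lists the share that was higher had a median of 26.4% and a highest value of 45.8%. The larger share could reflect an effect of the genotype shared by both KO populations, but tissue differs with genotype in the second comparison and stays open. Raised genes silent in control IELs, such as Cpxm1, passed the filter only through their level in KO spleen cells, which can raise the share. The lists were matched on mean expression alone and need not share this effect.

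Gut epithelial markers were highest in control IEL replicate 3, by a median ratio of 3.90 over the mean of replicates 1 and 2 in all 11 members. Without Epcam and Lgals4 their sums were 17.6, 17.1 and 102 CPM in replicates 1, 2 and 3. A rise of all low-level genes in that library is excluded, since the highest of 10000 matched lists had a ratio of 1.55. Epithelial cells or their RNA in that library are a candidate source, although the sort took CD45-positive cells, and no biological explanation was tested.

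The 6 libraries of each comparison make 10 splits of 3 and 3, too few for a share under 0.05, and the real split alone (1 of 10) gave as many genes and as many lists in each comparison. edgeR called 1911 genes in KO against control IELp, 9639 in control IELs against IELp, 8660 in KO spleen cells against control IELs and 6700 in KO spleen cells against KO IELp, and the highest of the other splits was 0 by edgeR in each. At an unadjusted p under 0.05 edgeR's highest other split held 667, 231, 191 and 196 genes, against 3764, 10106, 9309 and 7616 in the real ones. Every other split mixes the real groups, so genes that differ between them add to the spread within its groups. A low count of genes there was largely fixed in advance and does not measure chance calls. The lists past camera's threshold numbered 10, 14, 14 and 13, and the highest of the other splits 6, 11, 8 and 12.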
